A study of Mus musculus with 26 samples.

How the data were processed

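RNA from mouse germinal vesicle (GV) oocytes, the fully grown oocytes arrested before the resumption of meiosis, was measured by sequencing of cDNA from polyadenylated RNA. Each library held a pool of 10 oocytes, and the labels call the pools of a group biological replicates. The table held 26 libraries in 7 groups: 6 from oocytes with a floxed low-complexity domain (LCD) of Tet3 and no Cre (WT), 7 with the same allele and the oocyte-specific Zp3-Cre transgene (LCD KO), 5 in which the labels add an HD mutation (HD mutant, with HD not defined in the sources used here), 2 with floxed Dnmt3a and Zp3-Cre (Dnmt3a KO), 2 with both floxed alleles and Zp3-Cre (DKO), 2 labelled Tet3 KO and 2 labelled as lacking Tet1, Tet2 and Tet3 (TKO). Every group except WT carried Zp3-Cre. The labels assign the libraries to 3 batches: WT 1 to 3 and LCD KO 1 to 3 in batch 1, WT 4, LCD KO 4 and 5 and HD mutant 1 to 3 in batch 2, and WT 5 and 6, LCD KO 6 and 7 and all Dnmt3a KO, DKO and Tet3 KO libraries in batch 3. No batch was stated for HD mutant 4 and 5 or for the TKO libraries.

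The deposited values were raw read counts per gene symbol, with no normalization by the authors. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.5.0, aligned with HISAT2 2.1.0 to mm9 and counted with featureCounts 1.6.4. The annotation, the strand setting and the treatment of reads with several alignments were not given in the sources used here, so near-identical gene copies, overlapping genes and antisense genes carry counts that cannot be assigned with certainty. The table had 24542 features, of which 92 were ERCC spike-in sequences that held 1 count over the 24 distinct libraries. These were left out, which left 24450 features, among them Cre and GFP sequences.

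The counts of each library were compared before any averaging. The 2 TKO columns held values identical to the 2 Tet3 KO columns in all features, whereas the 50 other pairs of libraries of the same group differed with a chi-square per degree of freedom of at least 3.63. Each identical pair was counted once, so that 24 distinct libraries entered any analysis.

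Total counts were 3329734 to 4309573 per library in batch 1, 5403852 to 7833087 in batch 2, 2558479 to 4144414 in batch 3 and 1838824 to 3914953 where no batch was stated. A count of 0 was read as up to 3 counts over the libraries of a group. Fold changes against a group at 0 were computed from that floor and are given as lower bounds, from the libraries of the batches in which both groups were present. Floors cover counting error only, because the reads carried no molecular identifiers.

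Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter by group, robust dispersion estimates and terms for group and batch, over the 22 libraries with a stated batch. The filter kept 11794 genes, and the fit left 14 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. All adjusted p-values of single genes come from this test unless DESeq2 is named. TKO was compared with WT by the same test without a batch term over 24 libraries and 11836 genes. Levels are given as CPM (normalised for library size) computed from the counts with TMM factors, as mean ± SD over libraries, and fold changes on the log2 scale ± standard error. Levels pool the batches of a group unless a batch is named. Fold changes from the fit with a batch term are adjusted for batch and can differ from the ratio of such levels. Because WT and LCD KO occur in all 3 batches, they link the groups found in a single batch. TMM factors lay between 0.729 and 0.755 in batch 1 and between 1.03 and 1.19 in the other stated batches.

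Gene lists were fixed before the data were examined, as were the design, the rule for naming genes and most alternatives. They cover DNA methylation machinery, genes sensitive to methylation in the germline, imprinted genes with maternal methylation, oocyte and maternal-effect genes, maternal mRNA decay, meiotic maturation, genes of the activation of the 2-cell embryo genome, histone modifiers, base excision repair, p53 and DNA damage, apoptosis, stress and chaperones, oxidative phosphorylation, ribosomal proteins, trophoblast genes, and markers of granulosa or cumulus cells, theca or stroma, and blood or immune cells. Of 19 lists, 17 were tested; the list of genes encoded in mitochondria had 0 members in the table and the blood and immune list had under 3 measured members. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over lists within a comparison. Fry tests whether the genes of a set move, on balance, in 1 direction and does not compare them with other genes.

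Genes were named by a rule: the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM in the higher group, a regular symbol and every library on the same side of the reference mean of its batch, then Tet1, Tet2, Tet3 and Dnmt3a, and up to 4 members of each list with the smallest p. For LCD KO against WT, Kit, Dnmt1, Majin, Tex15, Gclc and Mtfr2 fell outside the rule and were chosen after their values were seen, as was the level of Klf10 in HD mutant; these were not followed through the alternatives.

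The genes called between LCD KO and WT in batches 1 and 2 alone were measured in batch 3, and those called in batches 1 and 3 alone were measured in batch 2, so that the libraries that chose a gene did not measure it. Overlaps of calls between comparisons that shared WT libraries were set beside the overlap of independent lists and the overlap with the WT libraries split. Neighbouring genes were taken from the order of genes in GRCm38, with names matched for 97.4% of tested genes; no coordinates are given, since the counts refer to mm9.

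The alternatives were DESeq2 1.42.0, median-of-ratios size factors, no low-count filter, a minimum mean of 1 CPM, no batch term, all distinct libraries, only the groups compared, single batches, the replicate number as a block, and each library left out in turn. A fit without the 2 libraries labelled Tet3 KO and a fit of batches 1 and 3 only were chosen after seeing the data. The steps were tested on simulated counts with known changes, on 11554 genes. In LCD KO against WT, 64.6% of genes changed 2-fold and 98% of those changed 4-fold were recovered, against 31.3% and 90% in HD mutant against WT, 24% and 75.5% in Dnmt3a KO against WT, 16.7% and 78% in DKO against Dnmt3a KO and 16% and 71.4% in DKO against LCD KO. At most 6 of 11128 unchanged genes were called in any of these simulated comparisons with a batch term. The simulated counts were drawn from the model that the test assumes, with the batch effects of the fit. They therefore do not show the rate of false calls in the real counts.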

Results

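Polyadenylated RNA was sequenced from pools of 10 mouse GV oocytes in which Tet3, a dioxygenase that oxidizes methylated cytosine, or Dnmt3a, the de novo DNA methyltransferase of the oocyte, had been altered with Zp3-Cre. Total counts ranged from 1838824 in HD mutant 5 to 7833087 in LCD KO 5, and between 12948 and 15510 genes were detected per library. Batch 2 was sequenced more deeply than the others, and its share of counts on Rn45s, a ribosomal RNA precursor, was 1.14% to 3.11%, against at most 0.714% in the other libraries.

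The targeted genes were measured in every library. Tet3 averaged 248 ± 95.6 CPM in WT (SD, n = 6) and 91.6 ± 63.1 in LCD KO (n = 7), 117 ± 71.3 in HD mutant (n = 5) and 61.4 ± 6.05 in DKO (n = 2). Its count fell by 1.78 ± 0.21 on the log2 scale in LCD KO (adjusted p = 6.32e-06). Counts per gene cannot tell a fall of the transcript from reads missing in the deleted part. The log2 fold change was -1.86 ± 0.33 in HD mutant (adjusted p = 0.00149) and -1.73 ± 0.36 in DKO (adjusted p = 0.00748). The fall in LCD KO was present in each batch, with means of 49.9 against 229 CPM in batch 1, 182 against 427 in batch 2 and 64.1 against 188 in batch 3. Dnmt3a averaged 339 ± 144 CPM in WT, 120 ± 18.1 in Dnmt3a KO (n = 2) and 98.5 ± 1.72 in DKO. Its log2 fold change was -1.53 ± 0.20 in Dnmt3a KO (adjusted p = 6.56e-05), -1.81 ± 0.20 in DKO (adjusted p = 2.79e-06) and 0.10 ± 0.12 in LCD KO (adjusted p = 0.593). In the libraries labelled Tet3 KO, the Tet3 count was not lower than in WT. It stood at 310 ± 67.3 CPM (n = 2), with a log2 fold change of 0.60 ± 0.33 against WT (adjusted p = 0.650). Counts per gene do not show whether a part of the transcript was missing. In the same libraries Dnmt3a stood at 124 ± 26.8 CPM and fell by 1.48 ± 0.20 (adjusted p = 4.1e-05). Tet1 and Tet2 were low throughout, at 4.10 and 3.65 CPM in WT. The p-values of single genes and of fry measure the spread between pools of 10 oocytes that the labels call biological replicates. For groups of 2 that spread is shared with the other groups of the fit. Camera at the preset correlation instead ranks the genes of a list against other genes.

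**Figure D1:**
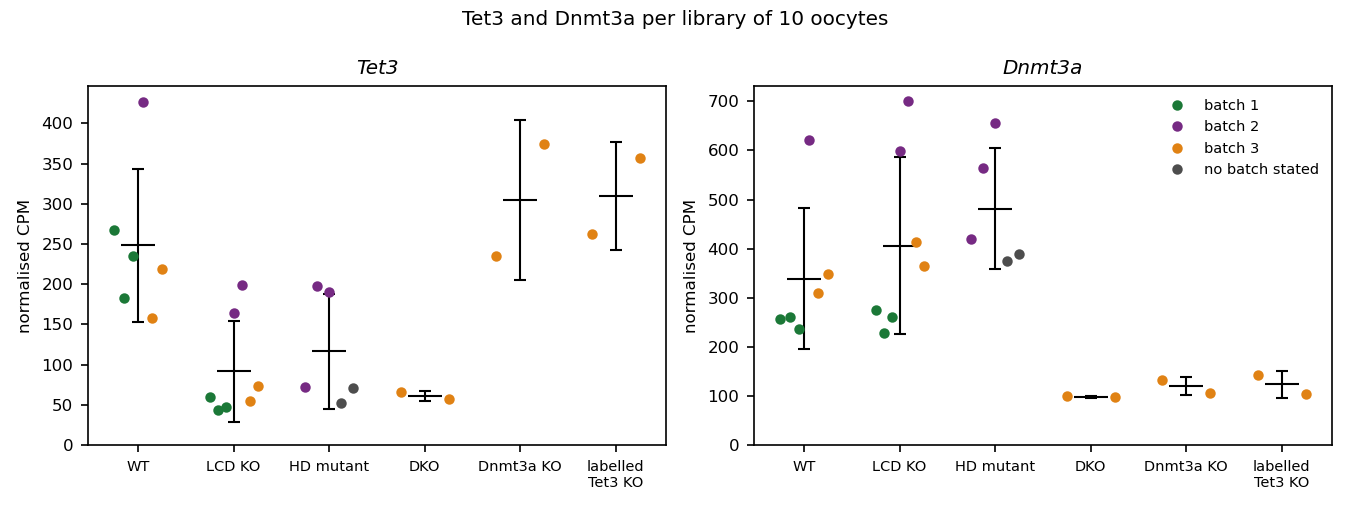
Normalised CPM of Tet3 (left) and Dnmt3a (right) in each distinct library, with points coloured by batch and a bar with whiskers for the mean ± SD of each group. Tet3 averaged 248 CPM in WT and 310 CPM in the libraries labelled Tet3 KO, where Dnmt3a averaged 124 CPM, close to the 120 CPM of Dnmt3a KO.

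The comparison of LCD KO with WT asked what removal of the Tet3 low-complexity domain does to the oocyte transcriptome. Some of the genes that the oocyte stores for early development fell. Of 42 measured oocyte and maternal-effect genes 18 fell, 0 rose and 24 did not pass, and 22 fell when adjusted over the list alone; the list as a whole passed camera (adjusted p = 2.82e-07) but not when the correlation was estimated (adjusted p = 0.13 with an estimated correlation). The genes that fell included Mos, the kinase that drives MAPK signalling in the maturing oocyte (log2 fold change -0.77 ± 0.12), and Cpeb1, a regulator of cytoplasmic polyadenylation (-0.83 ± 0.14). Others were Tle6, a member of the subcortical maternal complex (-0.76 ± 0.15), and Kit, the receptor for stem cell factor (-1.40). Klf10, a zinc finger repressor induced by TGF-beta, rose by 3.48 ± 0.14, from 7.11 ± 1.32 CPM in WT (n = 6) to 76.4 ± 15.3 in LCD KO (n = 7). Its batch means were 87.2 against 7.75, 59.5 against 5.20 and 77.1 against 7.10 CPM. Tmem47, which encodes a membrane protein of cell junctions, fell by 3.66 ± 0.23, from 25.1 ± 8.54 to 1.92 ± 1.42 CPM.

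In all, 2162 of 11794 genes (18.3%) were called in LCD KO, 1049 higher and 1113 lower, with a median absolute log2 fold change of 0.69 among them. Of these, 574 changed at least 2-fold. Mt1, a metallothionein, was higher by 7.93 ± 0.24 and is described with the transgene below. Besides Klf10, large rises were those of Abcb11, the bile salt export pump (3.61 ± 0.73), Sectm1a (3.43 ± 0.57), Ppp1r1b, an inhibitor of protein phosphatase 1 (3.19 ± 0.68), and Galnt13, a glycosyltransferase that starts O-linked chains (2.87 ± 0.41). They were followed by Tyr, the tyrosinase of melanin synthesis (2.78 ± 0.78), and Cntn5, a neuronal adhesion protein (2.73 ± 0.47). Large falls were seen for Cdc42ep3, an effector of Cdc42 (-3.14 ± 0.30), the transcription factors Ebf2 (-2.96 ± 0.67) and Zfp521 (-2.96 ± 0.38), Neto2, an auxiliary subunit of kainate receptors (-2.85 ± 0.51), Tril (-2.76 ± 0.54) and Bend3 (-2.69 ± 0.58). Hist1h4b (2.54 ± 0.58) and the olfactory receptor genes Olfr1349 (-3.01 ± 0.64) and Olfr877 (-2.77 ± 0.55) were also called, but belong to families with near-identical copies.

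The oocyte and maternal-effect list had a median log2 fold change of -0.30 in this comparison, and fry gave an adjusted p of 4.4e-05. Fry passed 8 of the 17 lists here, 5 lower, among them DNA methylation machinery (adjusted p = 0.00938) and imprinted genes (adjusted p = 0.0157), and 3 higher. The latter included apoptosis (adjusted p = 0.0425), although its median was -0.06 and camera gave an adjusted p of 0.389. None of the other 16 lists passed camera in this comparison, and with an estimated correlation 0 lists were called in any comparison. Of 24 genes of the DNA methylation machinery 6 fell and 0 rose (8 fell over the list alone). Among them were Tet3, Dnmt1, the maintenance methyltransferase (-0.59), Kdm1b, the histone demethylase that precedes imprint methylation (-0.44), and Hells (-0.54). Tet3 was altered by design, so its fall adds to the result of this list, which was not tested without it. Of 34 genes of maternal mRNA decay 6 fell, including Cnot6l, a deadenylase (-0.57), and 28 did not pass (6 fell over the list alone). Among 36 germline genes sensitive to methylation 7 rose and 3 fell (7 and 3 over the list alone). Sycp3, a protein of the synaptonemal complex, rose by 1.43 ± 0.24, and Majin, which tethers meiotic telomeres, by 1.61, whereas Tex15 fell (-0.74). Of 15 genes of the 2-cell genome activation list 1 rose and 3 fell (1 and 4 over the list alone), with Zscan4d at -1.79 ± 0.33 and Dppa2 at 0.39. Of 25 imprinted genes with maternal methylation 3 fell, Commd1, Blcap and Trappc9, and 22 did not pass (3 fell over the list alone). In batch 2 alone, with 1 WT library, Blcap (0.16), Trappc9 (0.15) and Hells (0.11) had the opposite sign.

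Stress genes moved in both directions. Of 37 stress and chaperone genes 9 rose and 6 fell (10 and 7 over the list alone). Rises included Hspb1, a small heat shock protein (1.79 ± 0.23), Xbp1, a factor of the unfolded protein response (1.24 ± 0.24), and Ddit3 (1.01). Gclc, the rate-limiting enzyme of glutathione synthesis, fell (-1.64). In the p53 and DNA damage list 5 of 30 genes rose and 3 fell (8 and 3 over the list alone), led by Ccng1 (1.62 ± 0.28) and Sesn1 (1.54 ± 0.34), both p53 targets. The remaining lists held few called members. Of all tested genes 18.3% were called in this comparison, so a few called members do not mark a list as changed. Of 47 meiotic maturation genes 5 rose and 2 fell (4 and 1 over the list alone), and of 38 histone modifiers 1 rose, Kmt2a (2.53 ± 0.50), and 5 fell (2 and 5). In addition 4 rose and 1 fell of 26 base excision repair genes (4 and 1), with Mbd4 at 0.72, and 4 rose and 1 fell of 25 apoptosis genes (4 and 1), with Mlkl at 1.36. Of 68 oxidative phosphorylation genes 2 rose and 1 fell (2 and 0 over the list alone). Of 72 ribosomal protein genes 3 rose and 0 fell (0 and 0), and of 11 trophoblast genes 1 rose and 1 fell (1 and 1), Tpbpa (2.14 ± 0.57) and Psg17 (-0.68). Markers of other ovarian cells showed 1 rise among 11 granulosa or cumulus genes, Hsd3b1 (0.99, 3 rises over the list alone), and 1 among 5 theca or stroma genes, Dcn (2.08, 1 over the list alone). The number of called genes was 544 without the batch term. It was 187 with the replicate number as a block, in which number 5 joined WT of batch 3 with LCD KO of batch 2. Single batches gave 2851 in batch 1, 12 in batch 2 (1 WT library) and 88 in batch 3.

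**Figure D2:**
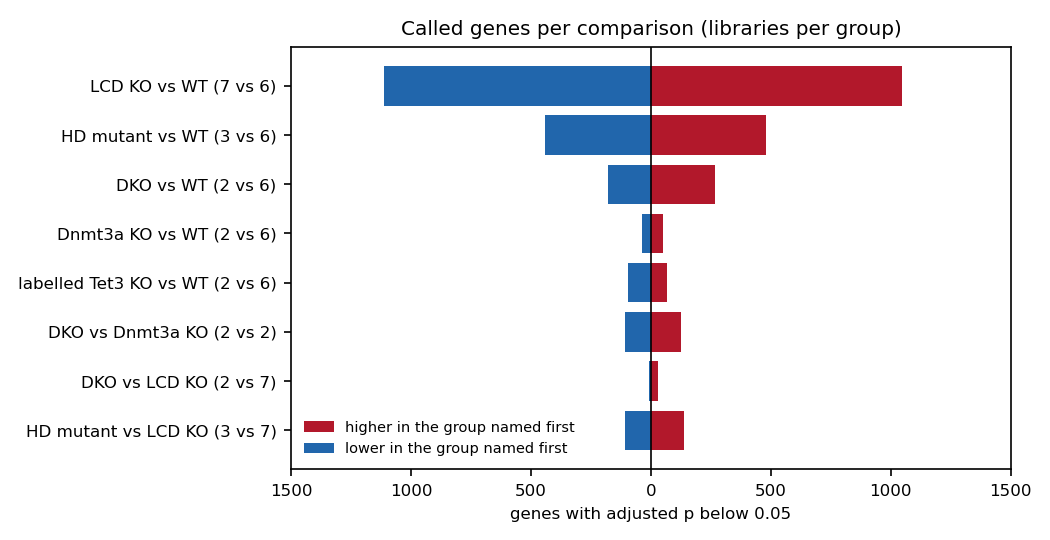
Number of genes with an adjusted p below 0.05 in 8 comparisons, with higher genes to the right and lower genes to the left of 0 and the number of libraries per group in parentheses. LCD KO against WT had 1049 higher and 1113 lower genes, and DKO against LCD KO had 28 and 9.

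**Figure D3:**
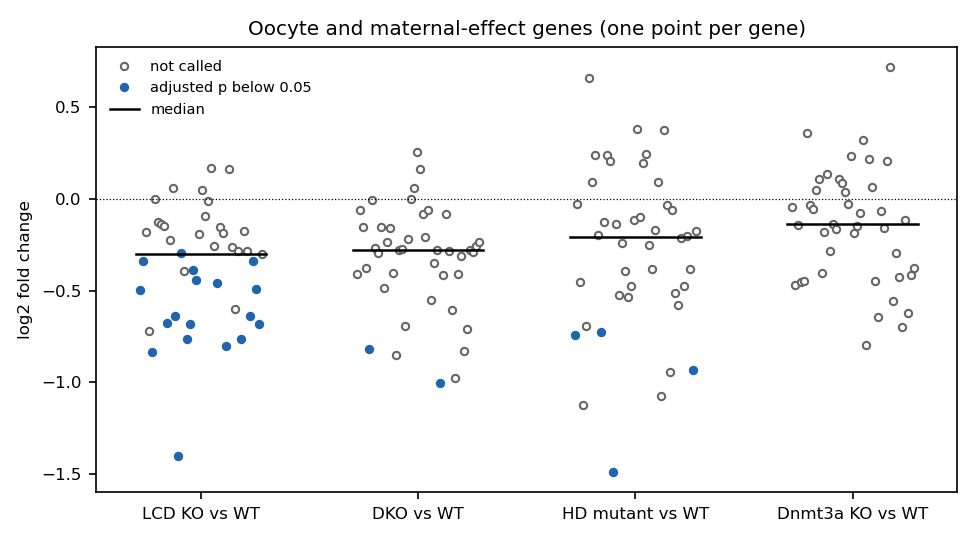
Log2 fold changes of the 42 oocyte and maternal-effect genes in 4 comparisons, each point a gene, filled where the adjusted p was below 0.05, with the median as a line. The medians were -0.30 in LCD KO, -0.28 in DKO, -0.21 in HD mutant and -0.14 in Dnmt3a KO.

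The genes called in LCD KO were followed in libraries that had not chosen them. Batches 1 and 2 alone called 1688 genes, 822 higher and 866 lower. In batch 3, the 811 measured genes of the higher set had a median log2 fold change of 0.47 in LCD KO, 0.49 in DKO, 0.04 in Dnmt3a KO and -0.06 in the libraries labelled Tet3 KO. The 842 genes of the lower set had medians of -0.42, -0.38, -0.04 and 0.08. Fry called both sets in LCD KO and in DKO (adjusted p = 0.00465 each). It called neither in Dnmt3a KO (adjusted p = 0.808 and 0.853) nor in the libraries labelled Tet3 KO (adjusted p = 0.808 and 0.530). Between DKO and Dnmt3a KO, which both carried Cre, the medians were 0.48 and -0.37 (adjusted p = 0.00465 for both). Across 10806 genes, which are not independent replicates, the fold changes of LCD KO in batches 1 and 2 were correlated with those of batch 3. Pearson's r was 0.542 for LCD KO, 0.516 for DKO, 0.0863 for Dnmt3a KO and -0.000368 for the libraries labelled Tet3 KO.

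**Figure D4:**
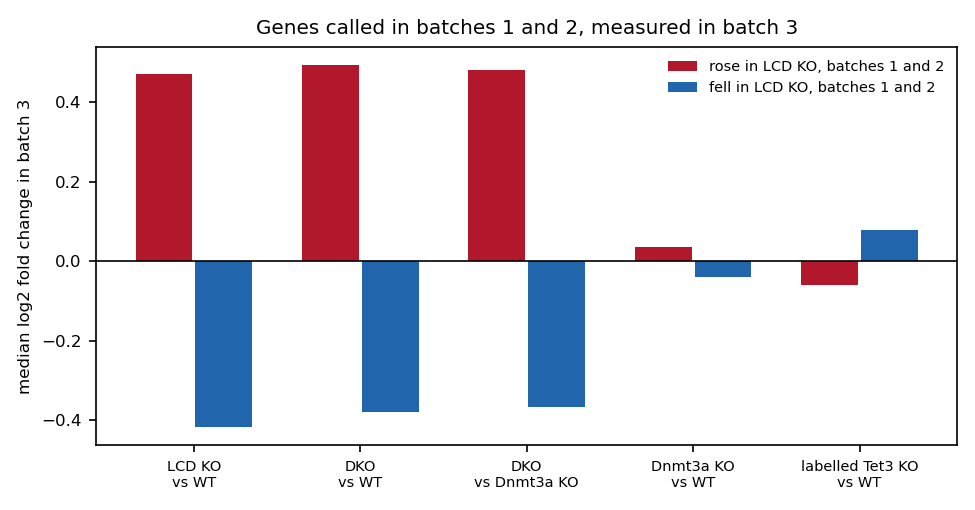
Median log2 fold change in batch 3 of the genes that rose or fell in LCD KO in batches 1 and 2, for 5 comparisons. The medians were 0.47 and -0.42 in LCD KO and 0.49 and -0.38 in DKO, and lay between -0.06 and 0.08 in Dnmt3a KO and in the libraries labelled Tet3 KO.

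Dnmt3a KO, which unlike WT also carried Zp3-Cre, was compared with WT. By the labels WT carried the floxed Tet3 domain and Dnmt3a KO floxed Dnmt3a, and differences between the mouse lines were not tested. Methylation itself was not analysed here. Pxdn, a peroxidase that crosslinks collagen IV, had 0 counts in both Dnmt3a KO libraries against 18.9 ± 14.2 CPM in WT (n = 6), at least 24.5-fold lower, and Npl, a lyase of sialic acid, was at least 17.8-fold lower. Tex9 rose by 3.33 ± 0.49, from 3.04 ± 1.08 to 27.4 ± 5.91 CPM (n = 2), and Qpct, a glutaminyl cyclase, by 4.26 ± 0.73. In DKO, which also lacked Dnmt3a, Pxdn and Npl were detected, at 12.3 and 1.71 CPM. Qpct was higher than in WT there as well (3.23 ± 0.78). Of 25 imprinted genes with maternal methylation 1 was called, and 2 rose and 1 fell over the list alone. The called gene was Sgce, expressed from the paternal allele (3.16 ± 0.72), from 1.01 ± 0.67 CPM in WT to 3.63 ± 0.585. The WT level pools 3 batches, whereas Dnmt3a KO is of batch 3 only, so the levels do not give the same ratio as the fold change. A total of 89 genes were called, 51 higher and 38 lower.

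Further rises in Dnmt3a KO were those of Nav1, a neuron navigator (3.67 ± 0.61), Manba, the lysosomal beta-mannosidase (3.21 ± 0.63), and Mettl7a1 (2.79 ± 0.44). Gcc1, a golgin (2.37 ± 0.51), and Pdha2, a testis form of pyruvate dehydrogenase (2.28 ± 0.51), also rose, and Reg2 was at least 13.7-fold higher. Manba (-4.95 ± 0.82) and Reg2 (at least 13.8-fold) were lower in DKO than in Dnmt3a KO. Their rises were therefore not shared by both groups that lacked Dnmt3a. Falls included Ptprv, at least 13.9-fold lower, Got1l1 (-3.80 ± 0.52), Fmo6 (-3.22 ± 0.42), Fbxo16 (-2.93 ± 0.45) and Slc5a10 (-2.76 ± 0.68). Smaller falls were those of Rad51b, a factor of homologous recombination (-2.35 ± 0.51), and Arntl2, a circadian transcription factor (-2.28 ± 0.41). Of 36 germline genes sensitive to methylation 2 fell and 0 rose (3 and 1 over the list alone). They were Mael, a piRNA factor (-0.87), and Tuba3b, an alpha-tubulin with a near-identical copy (-2.74 ± 0.42). Camera called 0 of the 17 lists. Of the 42 oocyte and maternal-effect genes (median -0.14) 0 were called by edgeR, over all genes or over the list alone, and 7 had an unadjusted p below 0.05. The count was 185 with DESeq2 and 32 without the batch term, and it was 26 without Dnmt3a KO replicate 2 and 56 without WT replicate 6.

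DKO oocytes, which lacked both the Tet3 domain and Dnmt3a, were compared with WT, with Dnmt3a KO and with LCD KO to ask how the effects combine. Against WT, Klf10 rose by 3.90 ± 0.20, to 105 ± 8.27 CPM (n = 2), and Zhx1, a zinc finger homeobox repressor, by 3.27 ± 0.30, from 8.05 ± 2.00 to 86.8 ± 28.2 CPM. Hspb1 (2.04 ± 0.32), Xbp1 (2.53 ± 0.34), Sesn1 (1.97 ± 0.47), Ccng1 (1.72 ± 0.42) and Kmt2a (2.81 ± 0.62) rose, as they had in LCD KO. Sgce (3.20) and Tuba3b (-4.09 ± 0.48) changed in the direction seen in Dnmt3a KO. In total 447 genes were called, 268 higher and 179 lower.

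Other rises in DKO were those of Bfsp1, a lens filament protein, at least 66.2-fold, Slc38a1, a transporter of neutral amino acids, at least 19.2-fold, and Mpdu1, at least 9.93-fold. Olfr283, of a family with similar copies, rose at least 16.2-fold, and smaller rises were those of Fut10, a fucosyltransferase (3.21 ± 0.51), Qpct (3.23 ± 0.78) and Aldh16a1 (3.23 ± 0.82). Bfsp1 also differed between batches in WT, at 1.62 CPM in batch 1 and 0 in the others. Large falls were those of Runx2, the bone transcription factor (-4.15 ± 0.80), Gjb2, a connexin (-4.31 ± 0.87), and Zfp521 (-4.03 ± 0.94). Further falls were those of Reg3g, an antimicrobial lectin (-4.62 ± 0.98), Plek (-3.93 ± 0.63), and E2f6, at least 4.03-fold lower. Of 42 oocyte and maternal-effect genes 2 fell, Pabpn1l and Cpeb1 (-0.82 ± 0.24), and 40 did not pass (4 fell over the list alone), with a median of -0.28. Camera gave an adjusted p of 0.000286 (adjusted p = 0.551 with an estimated correlation). In the p53 list 3 of 30 genes rose and in the stress list 2 of 37 (3 rises with 1 fall, and 2 rises, over the lists alone). The count was 164 without DKO replicate 1, 189 without replicate 2 and 257 without WT replicate 6, and 179 in batch 3 alone.

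Between DKO and Dnmt3a KO, 235 genes were called, 126 higher and 109 lower. Tet3 was lower in DKO (log2 fold change -2.31 ± 0.38, adjusted p = 0.00227), and Klf10 was higher by 3.27 ± 0.24, Hspb1 by 2.54 and Trp53, the p53 gene itself, by 1.56. Pxdn was at least 31.4-fold higher and Bfsp1 at least 70.7-fold higher. Trim6 (5.38 ± 0.91), Slc4a3, an anion exchanger (4.91 ± 1.13), and Rassf4 (3.68 ± 0.74) were also higher. Reg2, at least 13.8-fold lower, Manba (-4.95 ± 0.82), Plek (-3.78 ± 0.65), and Cldn9, a claudin (-3.76 ± 0.82), were lower. So were Pdgfrl (-3.37 ± 0.71), the transcription factors Tcf4 (-3.88 ± 0.93) and Isl1 (-3.05 ± 0.69), and Ednrb, an endothelin receptor (-2.79 ± 0.53). Of 30 genes of the p53 list 3 rose (5 rose and 1 fell over the list alone). The comparison rested on 2 libraries per group, and leaving out any of the 4 gave 78 to 115 calls; 20 genes were called without the batch term.

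DKO and LCD KO differed in 37 genes, 28 higher and 9 lower in DKO. Dnmt3a was lower (-1.91 ± 0.20), as were Tuba3b (-4.27 ± 0.49), Mfhas1 (-3.03 ± 0.59), Ifi30, a lysosomal thiol reductase (-2.40 ± 0.50), Arntl2 (-2.09 ± 0.42), and Nedd4l, a ubiquitin ligase (-0.94 ± 0.21). Mtfr2, a regulator of mitochondrial fission, was higher by 4.11 ± 0.27, at 442 ± 106 CPM against 63.3 ± 46.7 in LCD KO. The LCD KO level pools 3 batches, whereas DKO is of batch 3 only, so the levels do not give the same ratio. Slc38a1 (4.78 ± 0.97), Trim15 (2.82 ± 0.32), Gcc1 (2.69 ± 0.50), H2-Aa, a class II histocompatibility chain (2.20 ± 0.41), Rgl2 (2.02 ± 0.28) and Tmem47 (1.88 ± 0.35) were higher too. Camera called 0 of 17 lists, and the log2 fold change of Tet3 was 0.05 ± 0.34 (adjusted p = 0.991). At this depth 16% of simulated 2-fold changes were recovered in this comparison, so most changes of that size would be missed. The count was 12 without LCD KO replicate 7, 13 without DKO replicate 1, 19 without LCD KO replicate 6 or DKO replicate 2, and 72 with DESeq2.

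A test of whether the effect of the LCD differed with and without Dnmt3a called 8 genes. Mtfr2 fell in LCD KO against WT (-1.68) and was higher in DKO than in Dnmt3a KO (1.04), a difference of 2.72 ± 0.35 (adjusted p = 0.000102). Ccdc28a (2.06 ± 0.31), Rgl2 (1.87 ± 0.36) and Tmem47 (2.20 ± 0.42) also differed. The log2 fold change of Tmem47 was -3.66 in LCD KO and -1.46 between DKO and Dnmt3a KO. Pxdn and Npl were called because both had 0 counts in Dnmt3a KO and were detected in DKO, at 12.3 and 1.71 CPM. Mt1 and the Cre sequence were called because WT is the only group of the contrast without Cre. Any effect of Cre on the other genes would enter the contrast in the same way and was not separated. Camera called the oocyte and maternal-effect list (median 0.16, adjusted p = 0.0355, adjusted p = 0.885 with an estimated correlation), with 0 of 42 members called by edgeR and 7 at an unadjusted p below 0.05. Without WT replicate 4 the number of genes was 14, with DESeq2 33 and without the batch term 3; leaving out the other libraries in turn gave 6 to 12.

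HD mutant oocytes were compared with WT and with LCD KO to ask what the HD mutation adds. These results rest on HD mutant 1 to 3 of batch 2, which held 1 WT library. Through the batch term, HD mutant was also linked to WT of the other batches by way of LCD KO. Fold changes against WT therefore draw in part on the LCD KO libraries. Klf10 stood at 43.1 CPM in batch 2 (n = 3) against 5.20 in WT of that batch. Arid5b, a DNA-binding protein, fell by 5.29 ± 0.56, Isl1, a homeodomain factor, fell by 4.25 ± 0.58, and Grb14, an adaptor of receptor tyrosine kinases, rose by 4.45 ± 0.64. Tex15, a germ cell factor, fell by 2.09 on the log2 scale, and Mael rose (1.23). Of the 36 germline genes sensitive to methylation 3 rose, 3 fell and 30 did not pass (5 and 3 over the list alone). Altogether 923 genes were called, 481 higher and 442 lower.

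Among the largest rises in HD mutant were Asgr1, a subunit of the asialoglycoprotein receptor, at least 15.4-fold, Olfr1257, at least 7.03-fold, Pknox2 (5.36 ± 1.27), Qpct (5.13 ± 0.94) and Cyp2a12, at least 5.98-fold. Among the falls were Defb8, a beta-defensin, at least 105-fold, Dnm3, dynamin 3 (-8.86 ± 0.64), Prr18 (-5.58 ± 0.53), and Rhbdf1 (-4.87 ± 0.39). Tbx19 (-4.70 ± 0.64), Agpat4 (-4.35 ± 0.86) and Slc9a7 (-4.52 ± 1.09) also fell, as did Olfr877 (-5.86 ± 0.89). In HD mutant 4 and 5, which were outside the fit, Rhbdf1 (70.9 CPM) and Defb8 (10.4 CPM) lay near WT (77.7 and 15.8 CPM), so these falls were seen in 3 of 5 libraries. Several of these genes differed between batches in WT. Prr18 was at 37.7 CPM in WT of batch 2 and at 3.52 and 6.80 CPM in batches 1 and 3, and Dnm3 at 35.9 against 8.64 and 8.56 CPM. Of 42 oocyte and maternal-effect genes 4 fell, and 7 over the list alone. The 4 were Zp2, a zona pellucida protein (-0.93 ± 0.25), Figla (-0.72 ± 0.21), Ago2 (-0.74) and Kit (-1.49 ± 0.41). The median of the list was -0.21 and camera gave an adjusted p of 0.0391 (adjusted p = 0.869 with an estimated correlation). Kit had a log2 fold change of 0.25 without the batch term, so its direction depended on that term. Camera also called maternal mRNA decay (median -0.29, adjusted p = 0.0453), in which 1 of 34 genes fell, Exosc10 (-1.03). It called oxidative phosphorylation (median 0.20, adjusted p = 0.0453) too, in which 1 of 68 rose, Ndufv3 (1.05). The counts were the same over the lists alone, both had an adjusted p = 0.869 with an estimated correlation, and the oxidative phosphorylation median was -0.010 without the batch term. Maternal mRNA decay also missed the threshold of camera without that term (median -0.26, adjusted p = 0.0718).

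In the other lists for HD mutant, 4 of 37 stress and chaperone genes rose and 1 fell (5 and 1 over the list alone), among them Xbp1 (1.33 ± 0.33), Ddit3 (1.22) and Gpx4, a glutathione peroxidase that reduces lipid hydroperoxides (0.82). Of 24 DNA methylation genes 1 rose, Tet1 (1.47 ± 0.44), and 3 fell, Tet3, Dnmt3l (-0.70) and Setdb1 (-0.71), and 5 fell over the list alone. Setdb1 stood at 0.13 without the batch term. Dnmt3l stood at 0.56 with the replicate number as a block, which set HD mutant of batch 2 against WT of batch 1. The Tet1 result rests on a WT library of batch 2 at 1.08 CPM (6 counts), and HD mutant 4 and 5 stood at 1.45 and 4.02 CPM, below the WT mean of 4.10. Kmt2a rose (3.54 ± 0.62), and 0 of 25 imprinted genes were called by edgeR, over all genes or over the list alone, with 5 at an unadjusted p below 0.05. The count was 384 without HD mutant 1, 608 without WT replicate 4, 365 without the batch term, 113 with only the groups compared and 40 in batch 2 alone. When the genes called between LCD KO and WT in batches 1 and 3 (2051) were measured in batch 2, the 1006 of the higher set had medians of 0.46 in LCD KO and 0.52 in HD mutant. The 1028 of the lower set had medians of -0.30 and -0.28. The adjusted p for LCD KO and for HD mutant was 0.0984 for each set against the lone WT library, above the threshold. When only genes changed at least 2-fold were kept, the sets passed, with medians of 0.79 and -0.72 in HD mutant. WT was again the lone library, whose spread is not measured, so this does not settle the question.

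HD mutant and LCD KO differed in 245 genes, 138 higher and 107 lower in HD mutant, while Tet3 did not pass (log2 fold change -0.08 ± 0.30, adjusted p = 0.941). Cyp2c55 was at least 18.2-fold lower, and Arid5b (-5.05 ± 0.52), Rassf4 (-4.81 ± 0.60), Rhbdf1 (-4.68 ± 0.36), Cntn2, a neuronal adhesion protein (-4.07 ± 0.45), Folr2, a folate receptor (-4.37 ± 0.84), and Hspb1 (-1.98) were lower. Olfr1257, at least 22.5-fold, Asgr1 (4.32 ± 0.67), Myo7a, an unconventional myosin (4.63 ± 0.88), Cd40 (4.46 ± 1.19) and Lipt2, a lipoyl transferase (3.67 ± 0.30), were higher. Lipt2 stood at 33.1 CPM in HD mutant of batch 2 and at 3.14 and 1.26 CPM in LCD KO and WT of that batch, but at 16.9 to 30.1 CPM in LCD KO and WT of batches 1 and 3. Over the genes called in LCD KO in batches 1 and 3, HD mutant and LCD KO of batch 2 differed by medians of 0.047 and -0.0053 (adjusted p = 0.827 for both). Of 36 germline genes 1 was higher, Mael (0.79), and 1 lower, Tex15 (-1.35), with 2 each over the list alone, and camera called 0 of 17 lists. The count was 92 without LCD KO replicate 5, 97 without replicate 4, 156 without HD mutant 1, 162 without HD mutant 2, and 102 in batch 2 alone.

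The libraries labelled Tet3 KO were compared with WT and with LCD KO under their label. Their Tet3 count was not lower than in WT, so no direction here is attributed to loss of Tet3. Against WT, 162 genes were called, 65 higher and 97 lower. Pnpla3, a lipid droplet hydrolase, fell (-7.51 ± 0.39), from 620 ± 256 to 2.37 ± 0.241 CPM (n = 2), as did Pxdn (-6.37 ± 0.72), Npl, at least 20.3-fold, and Pdgfrl, at least 18.3-fold. Rises were those of Bfsp1, at least 82.4-fold, Qpct (4.51 ± 0.72) and Nav1 (3.16 ± 0.62). Ribosomal protein genes had a median of -0.17 (camera adjusted p = 0.0289, adjusted p = 0.769 with an estimated correlation), with 0 of 72 called by edgeR, over all genes or over the list alone, and 4 at an unadjusted p below 0.05. Against LCD KO, 895 genes were called, 474 higher and 421 lower in LCD KO, among them Pnpla3 (7.91 ± 0.39), Dnmt3a (1.58 ± 0.20), Mtfr2 (-3.53 ± 0.27) and Tet3 (-2.38 ± 0.32). In that comparison 9 of 36 germline genes were higher and 3 lower in LCD KO (10 and 4 over the list alone). Camera called oocyte and maternal-effect genes (median -0.28, adjusted p = 0.00546, adjusted p = 0.490 with an estimated correlation), though their median was 0.37 without the batch term. It also called oxidative phosphorylation (median 0.27, adjusted p = 0.00314) and ribosomal protein genes (median 0.24, adjusted p = 0.00546), both with adjusted p = 0.705 with an estimated correlation. Directly against Dnmt3a KO, a contrast added after the data were seen, 32 genes were called, with differences of 0.05 ± 0.21 for Dnmt3a and 0.02 ± 0.36 for Tet3, against 216 genes when set against DKO. Against WT the count was 55 and 69 without Tet3 KO replicates 1 and 2 and 105 without WT replicate 6, and against LCD KO it was 260, 277 and, without LCD KO replicate 6, 590.

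The TKO columns were identical to the Tet3 KO columns, and no batch was stated for them. Fitted without a batch term, 47 genes were called, 26 higher and 21 lower, including Pnpla3 (-8.01 ± 0.73), Npl, at least 21.2-fold lower, Tex9 (2.86 ± 0.47) and Pdha2 (2.64 ± 0.44). Tet3 had a log2 fold change of 0.32 ± 0.55 (adjusted p = 0.924), Tet1 -0.56 ± 0.61 and Tet2 0.94 ± 0.39, so none of the 3 targets passed the test. Oocyte and maternal-effect genes (median -0.72), oxidative phosphorylation genes (median -0.44) and ribosomal protein genes (median -0.59) passed camera with adjusted p = 7.22e-08, 1.07e-08 and 6.77e-13, and each had an adjusted p = 0.458 with an estimated correlation. With the batch term, the same counts under the Tet3 KO label gave 162 called genes, and medians of -0.08 (camera adjusted p = 0.449), -0.15 (adjusted p = 0.0633) and -0.17 (adjusted p = 0.0289) for these lists. The count was 816 when the libraries with no stated batch were taken as a further batch, and 10, 14 and 31 without TKO replicate 2, TKO replicate 1 or WT replicate 2.

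Called genes were shared between groups. LCD KO and HD mutant shared 337 higher and 245 lower genes, where independent lists would share 42.8 and 41.7, LCD KO and DKO shared 200 and 126 (23.8 and 16.9), and Dnmt3a KO and DKO shared 26 and 14 (1.16 and 0.577). LCD KO and Dnmt3a KO shared 14 and 6 (4.54 and 3.59) and went in opposite directions in 8 genes. Dnmt3a KO and the libraries labelled Tet3 KO shared 29 higher genes of 51 and 65, and 26 lower genes of 38 and 97 (0.281 and 0.313). These comparisons used the same WT libraries. With the WT libraries split between the comparisons, LCD KO and HD mutant shared 71 or 142 higher and 34 or 78 lower genes. For LCD KO and DKO the numbers were 74 or 76 and 42 or 51. For Dnmt3a KO and the libraries labelled Tet3 KO they were 13 or 14 and 14 or 18. Only WT was split, and the LCD KO libraries were not. Without the only WT library of its batch, HD mutant was linked to WT through LCD KO. With that library, as in the main fit, part of the link still runs through LCD KO. Part of the overlap of LCD KO and HD mutant, in the main fit and in the split, can therefore come from shared LCD KO libraries. Neither can separate that part, so the overlap is not independent agreement.

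Libraries with Cre were marked by Mt1, a metal-binding protein. Its level was 0.990 ± 0.481 CPM in WT (n = 6) and 276 ± 79.8 in LCD KO, 441 ± 127 in HD mutant, 233 ± 58.1 in DKO, 232 ± 69.6 in Dnmt3a KO and 194 ± 4.35 in the libraries labelled Tet3 KO. The log2 fold change against WT was 7.93 ± 0.24 in LCD KO and 8.12 ± 0.32 in Dnmt3a KO (adjusted p = 2.8e-19 in LCD KO). Cre sequence itself had 0 counts in all WT libraries and averaged 19.4 CPM in LCD KO of batch 1, and it had 0 counts in all 5 Cre libraries of batch 2.

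**Figure D5:**
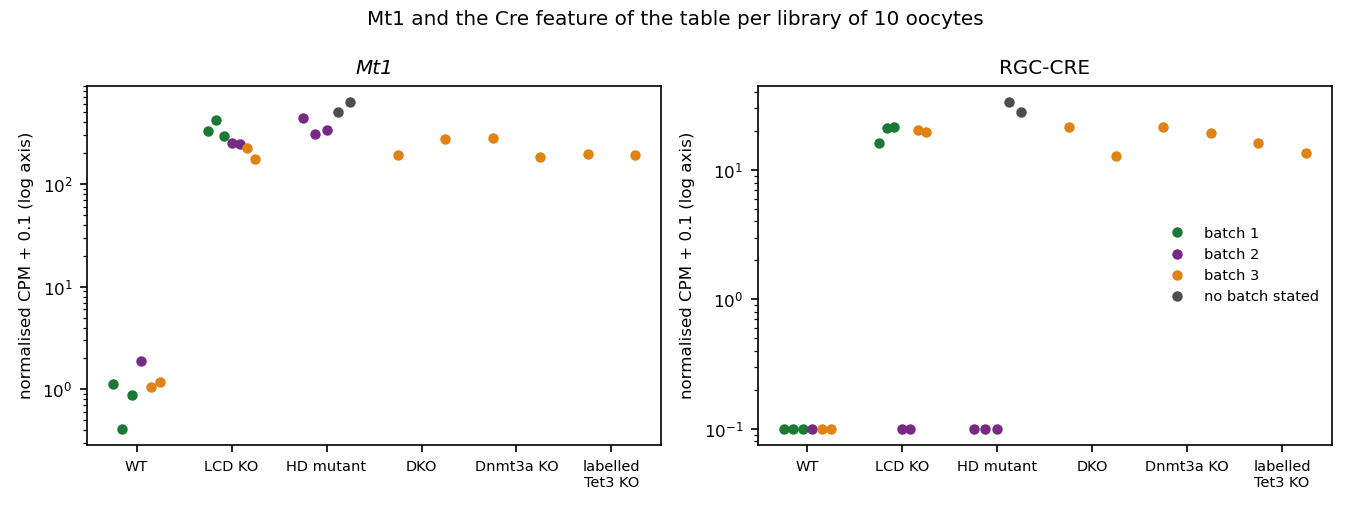
Normalised CPM plus 0.1 on a log axis for Mt1 (left) and for the Cre sequence of the table (right), each point a distinct library coloured by batch. Mt1 was at least 173 CPM in every library with Cre and at most 1.79 CPM in WT, while the Cre sequence was at 0 in batch 2.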

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

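The interaction was planned, and the tests of explanations and the splits of the libraries were chosen after the results were seen. For 8 measures in each of 3 groups of libraries, 24 sets of values in all, 3 sets held a value far from the rest, against a chance rate of about 1 in 20. WT replicate 4, the WT library of batch 2, had 3.11% of its counts on Rn45s, where the nearest WT library had 0.714%, and 620 CPM of Dnmt3a, where the nearest had 347 CPM. The other libraries of batch 2 held 419 to 701 CPM of Dnmt3a and 1.14% to 2.69% of Rn45s, so the Dnmt3a value was ordinary for its batch. LCD KO replicate 6 had 11.4 CPM of Tet1, where the nearest library had 5.33 CPM. The test of whether the effect of the LCD differed with and without Dnmt3a called 8 genes: Mtfr2, Ccdc28a, Rgl2, Tmem47, Pxdn, Npl, Mt1 and the Cre sequence. The contrast counts Cre unequally for every gene. For the last pair the difference follows from that design, and for the other genes an effect of Cre cannot be separated.

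A signal was also present in sequences that are not mouse genes. The Cre sequence had at least 38 counts in each of the 13 Cre libraries outside batch 2, and 0 in WT and in the 5 Cre libraries of batch 2, as did the GFP sequence in batch 2. These were the 2 features at 0 in those 5 libraries with a median above 5 CPM in the other Cre libraries. Mt1 was at least 247 CPM in those 5 libraries, so the 0 does not show that Cre was absent. Its cause was not tested. The GFP sequence averaged 25.1 CPM in DKO, 24.1 in HD mutant 4 and 5 and 17.3 in LCD KO of batch 3, but 0.919 in Dnmt3a KO and 1.04 in the libraries labelled Tet3 KO, with at most 2 counts in any WT library. No explanation was tested for the GFP signal.

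The libraries labelled Tet3 KO, whose values the TKO columns repeat, had WT-like Tet3 and low Dnmt3a. A lower Tet3 transcript is argued against as the reason for the low Dnmt3a, since Tet3 had a log2 fold change of 0.60 ± 0.33 against WT in these libraries. Their Dnmt3a level, which raised the question of a wrong label, was not used to test it. Of 324 genes called between Dnmt3a KO and LCD KO of batch 3, without Dnmt3a and Tet3, 63.0% moved the same way between these libraries and WT of batch 3, which share no library with the first set (median 0.19, past the threshold of fry, with 2 libraries per group). This cannot decide, because WT and LCD KO share the floxed Tet3 domain while Dnmt3a KO is labelled with floxed Dnmt3a. A difference between alleles or mouse lines could move these genes the same way. With no WT library shared, fold changes of these libraries correlated with Dnmt3a KO (Pearson's r 0.263 and 0.142) about as with DKO (0.235 and 0.138). A mislabelled genotype is a candidate explanation, though 32 genes differed from Dnmt3a KO. A Tet3 allele whose transcript stays at WT level, with Dnmt3a low for another reason, remains open.

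Mt1 was high in every library with Zp3-Cre, whatever gene was deleted. A metal response is argued against by Slc30a1, which metal also induces and which had a log2 fold change of -0.33 ± 0.19 in LCD KO, and by Mt2, with 11 counts over all Cre libraries. Sequence of the transgene counted as Mt1 stays open: the level that raised the question, at least 173 CPM in Cre libraries against at most 1.79 in WT, cannot decide it, and the sequence of the construct was not used here. In batch 2, where the Cre sequence was at 0, the lowest Cre library had 247 CPM of Mt1.

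The genes changed in LCD KO were weighed against Cre alone and against batch. Cre alone is argued against by the comparison of DKO with Dnmt3a KO, both with Cre, in which these genes moved in their direction by a median of 0.44. A batch difference is argued against by their median of 0.44 between LCD KO and WT within batch 3, which had not chosen them. In batch 2, with 1 WT library, the genes chosen in batches 1 and 3 had medians of 0.46 and -0.30 but missed the threshold (adjusted p = 0.0984 for both). The LCD deletion may therefore be their cause, as a hypothesis, with other differences between the mouse lines untested.

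Other splits of the same libraries were counted for the comparisons of at least 3 against 3. For LCD KO against WT, 100 of 1716 splits were counted, the real one among them. Only the real one, with 2162 genes, gave as many, which makes chance unlikely but does not exclude it. The highest other split, with 1390, put WT replicates 5 and 6 with 5 LCD KO libraries. Over 100 of the 360 splits that keep the numbers of each batch, 1 gave as many, again the real one, the highest other being 1423. For HD mutant against WT, 1 of 84 splits gave as many as the real 923, the highest other being 401, but these exchange libraries across batches. Splits within batches number 4, too few for a share under 0.05, with 0 genes as the highest other and 40 genes in the real comparison of batch 2 alone. For HD mutant against LCD KO, 2 of 100 splits gave at least the real 245, and the highest other split gave 751. That split set LCD KO replicates 1 and 2 with HD mutant 1, and a count so far above the real one points to a structure of the samples, whose cause was not tested. The highest other split of HD mutant against WT also held HD mutant 1, which stood apart within batch 2: it differed from HD mutant 2 and 3 with a chi-square per degree of freedom of 42.1 and 50.9, against 5.53 between those, and its Tet3 was at 72.0 CPM against 198 and 191. Against HD mutant 4 and 5, HD mutant 1 had 41.0 and 44.2, and HD mutant 2 and 3 had 84.7 to 97.1. Tet3 was at 52.0 and 70.7 CPM in HD mutant 4 and 5. The Cre sequence, at 0 in HD mutant 1, went with batch 2 instead. Whether HD mutant 1 belongs with batch 2 was not tested. For HD mutant against LCD KO, splits within batches number 10, too few for a share under 0.05, with 2 genes as the highest other. Within batch 2 alone the real comparison gave 102 genes.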

How the results depend on the processing

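The fits without the 2 libraries labelled Tet3 KO and of batches 1 and 3 only were chosen after the data were seen. Of 225 counts of called genes under the alternatives, 140 lay within 1.5 times the reported count and 85 did not; of 7558 values of named genes, 5971 kept their direction and side of the threshold, 1550 kept their direction and missed it, 3 newly passed it and 34 reversed. Without the batch term, LCD KO against WT gave 544 genes, the libraries labelled Tet3 KO against WT 60, Dnmt3a KO against WT 32, DKO against Dnmt3a KO 20, DKO against LCD KO 13, HD mutant against WT 365 and against LCD KO 96, LCD KO against the libraries labelled Tet3 KO 368, and the interaction 3. With all distinct libraries and no batch term the same comparisons gave 357, 47, 15, 4, 5, 405, 99, 232 and 2, and DKO against WT 167. TKO against WT gave 816 with a further batch for the libraries without one. Without the filter, which tests more genes, the libraries labelled Tet3 KO gave 284, Dnmt3a KO 311, DKO 672, DKO against Dnmt3a KO 449, DKO against LCD KO 122, HD mutant against LCD KO 410 and the interaction 70. DESeq2 gave 185 for Dnmt3a KO, 378 for DKO against Dnmt3a KO, 72 for DKO against LCD KO, 33 for the interaction and 90 for TKO. With only the groups compared, which uses fewer libraries, the libraries labelled Tet3 KO gave 276, DKO 285, DKO against Dnmt3a KO 132, DKO against LCD KO 56, HD mutant against WT 113 and TKO 28. Batch 2 alone gave 12 for LCD KO, 40 for HD mutant against WT and 102 against LCD KO; batch 3 alone gave 88 for LCD KO, 54 for Dnmt3a KO, 179 for DKO and 449 for LCD KO against the libraries labelled Tet3 KO; batches 1 and 3 only gave 57 for DKO against LCD KO and 16 for the interaction. Fits with fewer libraries called fewer genes in some comparisons and more in others, and the cause was not tested.

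The replicate numbers were not taken as pairs: of 6 numbers shared by WT and LCD KO, 5 WT libraries correlated best with an LCD KO library of another number, although within a batch those of the same number correlated by 0.169 to 0.705. With the replicate block, which is set here only as an alternative, LCD KO against WT gave 187 genes, the libraries labelled Tet3 KO 3012, Dnmt3a KO 2069, DKO 3873, DKO against LCD KO 2224, HD mutant against WT 2747 and against LCD KO 4345, LCD KO against the libraries labelled Tet3 KO 3957 and TKO 3012. The block kept only libraries that share a number. It thereby set libraries of batch 3 (Dnmt3a KO, DKO, labelled Tet3 KO) or batch 2 (HD mutant) against WT or LCD KO of batch 1. In these fits, and in TKO, which repeats the Tet3 KO columns, group and batch cannot be told apart. Their counts therefore do not show how stable the calls are. DKO against Dnmt3a KO, both of batch 3, gave 170. The block reversed Ifi30 in DKO against LCD KO (0.094), Rpl23 (-0.032) and Arg2 (-1.10) in HD mutant against LCD KO, and Mos in LCD KO against the libraries labelled Tet3 KO (0.96). In HD mutant against WT it reversed Trim30d (-0.26), Dnmt3a (1.11), Setdb1 (0.031), Dnmt3l (0.56), Kit (0.57), Tpx2 (-0.58), Numa1 (1.02), Sgo1 (-0.28), Exosc10 (0.13) and Sp110 (0.18). All these reversals lie in fits in which group and batch cannot be told apart.

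Other reversals came without the batch term: Aldh16a1 in the libraries labelled Tet3 KO (-0.0066), Arg2 in HD mutant against LCD KO (-0.43), Mos in LCD KO against the libraries labelled Tet3 KO (0.38), and in HD mutant against WT Dnmt3a (0.69), Setdb1 (0.13), Kit (0.25), Tpx2 (-0.32), Numa1 (0.48), Sgo1 (-0.15), Sp110 (0.29) and Mbd4 (-0.015). With all distinct libraries and no batch term Aldh16a1 (-0.0015), Dnmt3a in HD mutant (0.51), Arg2 (-0.29) and Mos (0.38) reversed. In batch 2 alone Hells (0.11), Blcap (0.16), Trappc9 (0.15), Neil3 (0.12) and Bik (-0.11) reversed in LCD KO. Of gene lists, the oxidative phosphorylation median in HD mutant (-0.010) and the maternal-effect median in LCD KO against the libraries labelled Tet3 KO (0.37) reversed without the batch term. Lists called without it numbered 3 in the libraries labelled Tet3 KO, 3 in Dnmt3a KO, 2 in DKO, 3 in DKO against LCD KO, 1 in HD mutant against LCD KO and 0 for the interaction; with an estimated correlation 0 lists were called by camera in any comparison. For the genes changed at least 2-fold among those chosen in batches 1 and 3, batch 2 gave medians of 0.82 and -0.89 in LCD KO, 0.79 and -0.72 in HD mutant, and -0.083 and 0.16 between HD mutant and LCD KO. The sets newly passed in LCD KO and in HD mutant, but both rest on the single WT library of batch 2, whose spread is not measured. The cause was not tested.

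With each library left out in turn, the counts ranged over 1685 to 2309 for LCD KO, 55 to 172 for the libraries labelled Tet3 KO, 26 to 116 for Dnmt3a KO, 164 to 471 for DKO, 78 to 115 for DKO against Dnmt3a KO, 12 to 41 for DKO against LCD KO, 384 to 1114 for HD mutant against WT, 92 to 277 against LCD KO, 260 to 876 for LCD KO against the libraries labelled Tet3 KO, 6 to 14 for the interaction and 10 to 47 for TKO. Small effects were mostly missed. In the simulated data 32.7% of 1.5-fold changes were recovered in LCD KO against WT and 6% in Dnmt3a KO against WT, which has fewer libraries. Depth was not varied in the simulation.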

Other observations

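The values here were chosen after the data were seen, and none was part of a planned comparison. HD mutant 4 and 5, for which no batch was stated, were set beside the genes called in HD mutant 1 to 3. Of the 10 largest rises named against WT, both libraries lay above the WT mean for 6, and of the 10 largest falls both lay below it for 9. Of all called genes this held for 346 of 481 higher (71.9%, against 33.5% of all tested genes) and 355 of 442 lower (80.3%, against 43.5%). The WT mean came from the same 6 WT libraries that had helped to choose these genes, and WT also lacks Cre. The shares can therefore exceed those of all tested genes without an effect of the HD mutation. As examples, Arid5b was at 5.95 CPM in HD mutant 4 and 5, at 8.51 CPM in HD mutant 1 to 3 and at 169 ± 43.0 CPM in WT (n = 6). Klf10 was at 53.9, 43.1 and 7.11 CPM, Grb14 at 14.4, 23.2 and 1.6, Asgr1 at 4.80, 8.42 and 0.429, and Isl1 at 0.287, 0.267 and 4.89. For a pair of other genes HD mutant 4 and 5 lay near WT: Rhbdf1 was at 70.9 CPM, against 2.09 in HD mutant 1 to 3 and 77.7 in WT, and Defb8 at 10.4, 0 and 15.8 CPM.

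Called genes lying within 5 tested genes of each other on a chromosome, in the order of GRCm38, were counted against 200 shuffles of the calls. The libraries labelled Tet3 KO against WT had 32 such pairs, where the shuffles had a mean of 10.5 and a highest of 22, and Dnmt3a KO against WT had 10 (3.08 and 8). HD mutant against LCD KO had 86 (24.7 and 39), HD mutant against WT 421 (350 and 403) and LCD KO against the libraries labelled Tet3 KO 448 (323 and 370). LCD KO against WT had 1964, within the highest of its shuffles (1895 and 1996), and DKO against WT 107 (82.0 and 110). No explanation was tested for the pairs.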
